A study of Mus musculus with 6 samples.

How the data were processed

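RNA-seq was analysed for 6 mouse brain tumor samples made by in utero electroporation, in which DNA constructs are injected into the brain of an embryo and driven into its cells by an electric pulse. Per the labels, the tumors carried a mutant Pdgfra (named PdgfraD482V in the titles) and a dominant-negative p53, with or without FOXR2, a forkhead transcription factor, in CD-1 mice. Tumor RNA was selected for poly(A) tails, made into libraries with a kit that keeps strand and sequenced as single reads of 51 bases, per the labels' protocols.

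The deposited table holds whole-number read counts for 24537 gene symbols, of which 23609 were current RefSeq mouse symbols and 797 were older synonyms. Another 23 rows held dates, as a spreadsheet makes of some symbols, and were never named. TopHat and DESeq2 are named in the submitters' processing notes without versions. The same notes name hg19, a human build, although the symbols are those of mouse genes, so no coordinates are given. The counting tool, the annotation, the handling of reads that map to several places and the use of strand are not given in the sources used here. Ribosomal protein genes, clustered protocadherins, hemoglobins, the H2 genes of the MHC and zinc finger genes such as Zfp979 have near-identical copies or overlapping transcripts, and their counts are uncertain for that reason. The table had no row starting with mt-, so mitochondrially encoded mRNAs were not analysed here.

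Groups and replicate numbers were taken from the sample titles. A sample sheet deposited with the counts gives the opposite group for 6 of 6 libraries. Neither source could be checked against a decisive value, so libraries are called "titled FOXR2" and "titled Control" throughout. If the sheet is right, every direction given turns round.

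The libraries held 13429489 to 17927025 counts, and 3 counts (the floor used here) corresponded to 0.167 to 0.223 CPM (counts scaled to a common library size). Floors cover counting error only. Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a count minimum of 10, which left 13101, and TMM factors (0.961 to 1.03) were used. The quasi-likelihood F test compared the 3 libraries titled FOXR2 with the 3 titled Control with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are TMM-scaled, log2 fold changes are libraries titled FOXR2 minus titled Control with a prior count of 0.125, and ± after them gives the standard error. Nothing in the labels says whether the samples of a group came from separate animals, so p-values measure the spread between these samples.

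Before the data were examined, 32 gene lists were fixed. The 25 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with a correlation estimated for each list and with fry. Adjustment was over the 25 lists. Levels of Foxr2, Pdgfra and Trp53 were compared by an exact two-sided permutation test of log2(CPM + 0.5), whose smallest possible p with 3 against 3 is 0.1. The rule for named genes was also fixed then. It took the 3 construct genes, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM and non-overlapping groups, the 5 smallest p-values, any called ETS factor, and from each list the 3 members with the smallest adjusted p, or all tested members where there were 5 or fewer. Predicted genes, Rik clones, pseudogenes, small RNAs, immunoglobulin segments and unnamed identifiers were left out of the ranked parts. Some genes that the rule takes are not reported here.

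Alternatives listed then were DESeq2 1.42.0, RLE factors, total-count scaling, no filter on low counts, limma-voom, the replicate number as a block, and each library left out in turn. Added after seeing the data were animal sex as a covariate (read from Xist and Y-linked genes), an offset fitted to transcript length and GC content in each library with mgcv 1.9.3, and the groups of the deposited sheet. Transcript length and GC came from the GENCODE mouse annotation matched by symbol, and 99.4% of tested genes had both. On simulated counts for FOXR2 against Control with 200 of the genes changed, the edgeR test ran on 12940 genes and recovered 65% of 4-fold changes and 2% of 2-fold changes. It called 70 genes, of which 3 had not been changed. DESeq2 called 174 genes there, of which 61 had not been changed. Simulated genes varied independently and few were changed, so these shares need not hold for the real libraries.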

Results

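The transcriptomes of 6 mouse brain tumors were compared to ask how tumors with FOXR2 differed from tumors without it. All carried mutant Pdgfra and dominant-negative p53, and 3 libraries were titled FOXR2 and 3 titled Control. Depth ranged from 13429489 counts in FOXR2 replicate 3 to 17927025 in Control replicate 3. Gene levels correlated between libraries of the same title with Spearman values, across all 24537 rows, of 0.951 to 0.972, and between titles with 0.950 to 0.961. FOXR2 replicate 2 correlated more with Control replicate 1 (0.958) than with FOXR2 replicates 1 and 3 (0.951 and 0.954). FOXR2 replicates 1 and 3 likewise correlated more with Control replicate 1 (0.961 and 0.959) than with FOXR2 replicate 2. The first principal component held 39.8% of the variance and the second 24.9%. On the first, FOXR2 replicates 1, 2 and 3 lay at -50.3, -20.4 and -63.6. Control replicates 1, 2 and 3 lay at 33.9, 47.0 and 53.4. Counts differed by more than sampling noise in every pair of the same title, with a median chi-square per gene of at least 8.68. This speaks against a library deposited again and says nothing on whether the tumors came from separate animals. By the median chi-square, FOXR2 replicate 2 was nearer to FOXR2 replicates 1 and 3 (14.0 and 12.8) than to Control replicate 1 (16.6). The deposited sample sheet gives the opposite group for all 6 libraries, and every direction below holds for the titles and turns round if the sheet is right.

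The electroporated gene did not settle the labels. Foxr2 had 22, 1 and 7 counts in the libraries titled FOXR2 and 4, 10 and 7 in those titled Control, or 0.670 ± 0.700 against 0.414 ± 0.178 CPM (SD, n = 3 each; exact two-sided permutation p = 0.8, where 0.1 is the smallest possible). At this depth Foxr2 failed the filter on low counts, and a construct of another species or without the mouse untranslated regions need not give reads on this gene. Pdgfra, the receptor gene supplied to both groups, was abundant at 3120 ± 565 CPM in the libraries titled FOXR2 and 2190 ± 274 in those titled Control (SD, n = 3 each; exact permutation p = 0.2; edgeR adjusted p = 0.187). Trp53 stood at 304 ± 131 against 442 ± 104 CPM (SD, n = 3 each; exact permutation p = 0.3; edgeR adjusted p = 0.378). Neither difference passed its test.

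The largest increases in the libraries titled FOXR2 came to over 4 on the log2 scale. Sdk1, a synaptic adhesion molecule, averaged 17.4 ± 8.09 CPM in the libraries titled FOXR2 and 0.0996 ± 0.0911 in those titled Control (SD, n = 3 each), a log2 fold change of 7.35 ± 0.81 (edgeR adjusted p = 0.0283). Fam155a, a partner of the sodium leak channel, reached 47.1 ± 12.5 against 0.647 ± 0.493 CPM. Increases of 4.83 to 6.11 on the log2 scale were fitted for Car10, the forkhead gene Foxf1, the prohormone convertase Pcsk2, Islr, Palm2, Usp29, the hindbrain homeobox gene Hoxa2 and the clustered protocadherins Pcdhb3 and Pcdhb6. The smallest p-value belonged to B3gnt5, a glycosyltransferase of glycolipid synthesis, at 93.1 ± 1.20 against 3.47 ± 0.654 CPM (log2 fold change 4.74 ± 0.22, edgeR adjusted p = 0.000904). The ephrin receptor gene Ephb1 followed at 32.8 ± 0.649 against 4.58 ± 0.524 CPM (adjusted p = 0.0182), and Fam19a2 was higher by 3.88 ± 0.37. In the libraries titled Control, Sdk1, Car10, Pcsk2, Usp29 and Hoxa2 averaged below the level of 3 counts, so the size of their fold changes rests on few counts.

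The largest decreases were smaller. Zfp979, a zinc finger gene with near-identical copies, averaged 0.840 ± 1.03 CPM in the libraries titled FOXR2 and 21.8 ± 9.53 in those titled Control (SD, n = 3 each), a log2 fold change of -4.67 ± 0.90 (edgeR adjusted p = 0.0489). The transporter gene Slc35f2 stood at 2.22 ± 1.23 against 24.0 ± 6.93 CPM (adjusted p = 0.0388). H60b, a ligand of an activating receptor of natural killer cells, was lower by a log2 fold change of -3.37 ± 0.64, and Prodh, the proline-degrading enzyme, by -2.89 ± 0.52. Log2 fold changes of -2.81 to -2.09 were fitted for Echdc2, Nudt12, Mfsd10, Rgl3, Nexn, Cabp1, Cdc42ep5 and the lysine methyltransferase gene Setd6.

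**Figure D1:**
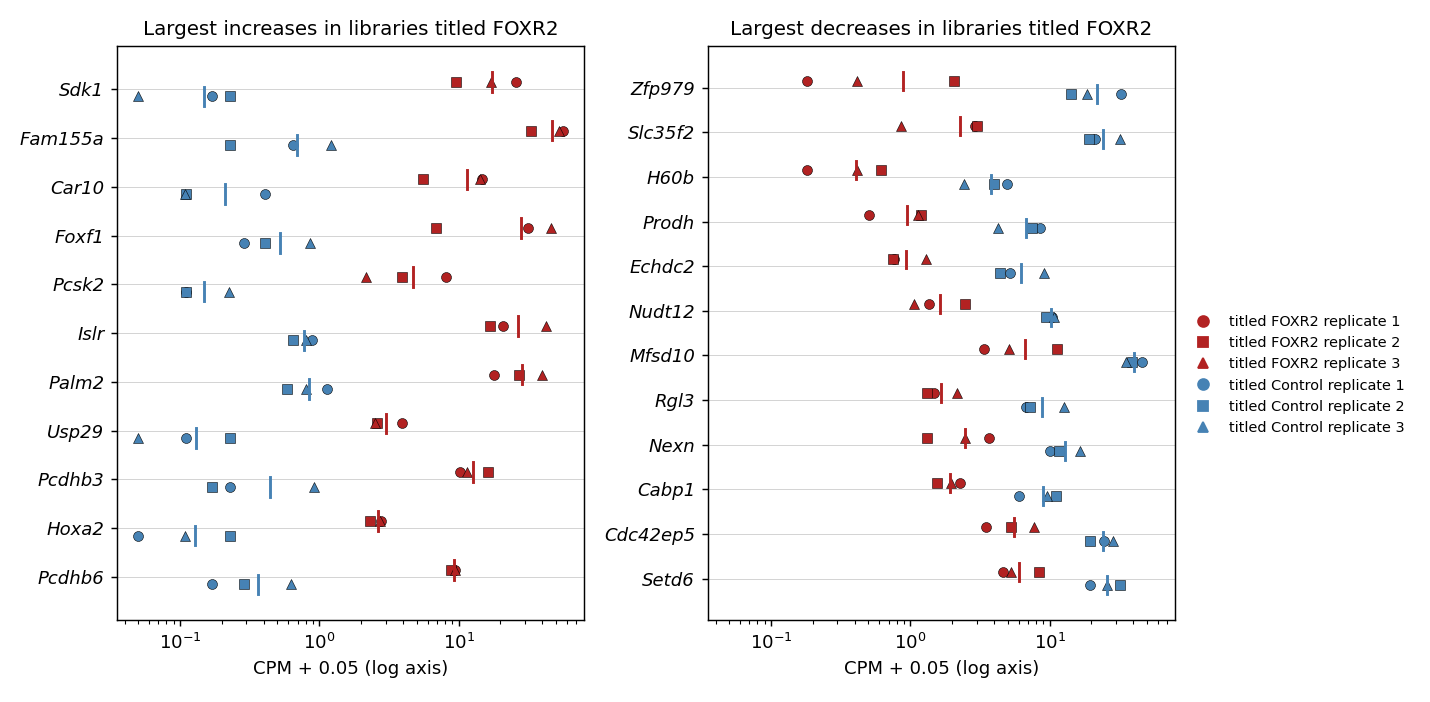
Each library's level (horizontal log axis, CPM + 0.05) of genes with the largest increases (left) and decreases (right), with red symbols for libraries titled FOXR2, blue for titled Control and vertical bars for group means. In each gene shown the groups do not overlap, with Sdk1 averaging 17.4 against 0.0996 CPM and Zfp979 0.840 against 21.8. The deposited sheet exchanges the groups.

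In all, edgeR called 119 genes higher and 181 lower in the libraries titled FOXR2 among 13101 tested, 112 and 165 of them at least 2-fold, and 3257 genes had an unadjusted p under 0.05. The groups did not overlap in 30.3% of tested genes, where chance gives 10%. The counts under the adjusted cutoff fell when nearly any library was left out. Without FOXR2 replicate 1, 2 genes were higher and 0 lower, without FOXR2 replicate 3 and without Control replicates 1 or 2 the counts were 1 and 0 each, and without Control replicate 3 they were 9 and 1, and 2241 to 2954 genes had an unadjusted p under 0.05 in these edgeR fits. Without FOXR2 replicate 2 there were 123 and 82. With animal sex as a covariate 7 were higher and 0 lower, with 2398 at an unadjusted p under 0.05, while DESeq2 called 947 in each direction. All 300 called genes kept their direction and an unadjusted p under 0.05 in each of these fits. The 300 were picked in these same libraries, and the groups did not overlap in any of them. Leaving out 1 library could hardly turn a direction, so this is no separate support.

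Genes for ribosomal proteins and ribosome biogenesis were lower as lists in the libraries titled FOXR2. All 73 tested genes of cytosolic ribosomal proteins had a fitted value below 0, with a median log2 fold change of -0.75. Of these, 6 were called lower over all genes and 58 adjusted over the list alone. Rps21 averaged 392 ± 47.4 against 967 ± 168 CPM, Rps18 1064 ± 67.7 against 2562 ± 593 and Rpl37a 453 ± 68.0 against 982 ± 142 (SD, n = 3 each; edgeR adjusted p = 0.0396, 0.0437 and 0.0451). With an offset for transcript length and GC 0 ribosomal protein genes were called by edgeR, where 3137 of all genes had an unadjusted p under 0.05, and these 3 had adjusted p of 0.0515, 0.0621 and 0.0828. Of 28 genes listed as MYC-driven ribosome biogenesis genes, 27 were fitted below 0, with a median of -0.74. Over all genes 4 were called lower, Phb2, the gene of a mitochondrial protein, included, and 13 adjusted over the list alone. Among them Ppan, needed for the large ribosomal subunit, fell from 92.1 ± 16.7 CPM in the libraries titled Control to 23.9 ± 3.96 in those titled FOXR2 (edgeR adjusted p = 0.0283). Tcof1, which acts in ribosomal DNA transcription, stood at 40.3 ± 3.98 against 153 ± 49.7 CPM (adjusted p = 0.0379) and Mybbp1a at 203 ± 21.5 against 429 ± 84.1 (adjusted p = 0.0489). Camera called both lists lower (adjusted p = 2.17e-24 and 2.23e-10), but with an estimated correlation the adjusted p was 0.596 for each.

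Cholesterol synthesis genes lay on the same side. All 15 tested members were fitted below 0 with a median log2 fold change of -0.56, 0 were called over all genes and 3 were called lower adjusted over the list alone. Among the smallest adjusted p were those of the synthesis enzyme Lss at 65.3 ± 12.9 against 150 ± 41.7 CPM and Insig1 at 118 ± 33.7 against 260 ± 43.4 (SD, n = 3 each; edgeR adjusted p = 0.0601 and 0.0657). Camera called the list lower (adjusted p = 0.000188), and with an estimated correlation its adjusted p was 0.619. At the preset correlation the calls of all 3 lower lists held in each of the fits without 1 library, which share most of their libraries. Fry did not call ribosomal proteins, ribosome biogenesis or cholesterol synthesis (adjusted p = 0.13, 0.13 and 0.282).

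Markers of immature neurons were higher as a list in the libraries titled FOXR2. Of 10 tested neuronal progenitor markers, 9 were fitted above 0 with a median log2 fold change of 1.17 (camera adjusted p = 0.00184, fry adjusted p = 0.0195). With an estimated correlation the camera adjusted p was 0.535. No member was called over all genes and 4 were called higher adjusted over the list alone. Dcx, a microtubule-associated protein of migrating neurons, stood at 188 ± 27.0 against 37.1 ± 32.5 CPM, Sox11 at 225 ± 73.9 against 91.8 ± 9.61 and Tubb3 at 119 ± 57.5 against 43.4 ± 10.2 (SD, n = 3 each; edgeR adjusted p = 0.0738, 0.0515 and 0.0952). Among 18 mature neuron markers, edgeR called Syt1, the calcium sensor of synaptic vesicles, higher at 81.9 ± 63.2 against 4.84 ± 2.39 CPM (adjusted p = 0.0436) and Syn1, a synaptic vesicle protein, higher by 1.32 ± 0.25 on the log2 scale (adjusted p = 0.0489). Nefm, a neurofilament gene, had a log2 fold change of -1.73 ± 0.51 (adjusted p = 0.102), 5 members were called higher and 1 lower adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.130), but was called higher without FOXR2 replicate 3 (adjusted p = 0.0447).

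Glial lineage lists gave no call with all libraries. The 21 oligodendrocyte precursor markers had a median log2 fold change of 0.10 (camera adjusted p = 0.154), with Ptprz1 at 1421 ± 129 against 705 ± 140 CPM (edgeR adjusted p = 0.0536) and 1 member called higher adjusted over the list alone. Without Control replicate 3 this list was called higher (median 0.52, camera adjusted p = 0.00519), and without Control replicate 2 its median was -0.14. Summed markers of mature oligodendrocytes varied within both groups, at 337, 5939 and 1659 CPM in FOXR2 replicates 1, 2 and 3 and 2041, 397 and 4454 in Control replicates 1, 2 and 3 (camera adjusted p = 0.894). Of 15 astrocyte markers the glutamate transporter gene Slc1a2 was called higher, at 82.3 ± 12.7 against 24.7 ± 6.72 CPM (SD, n = 3 each; edgeR adjusted p = 0.0379), while Aldh1l1 had a log2 fold change of -1.71 ± 0.62 (adjusted p = 0.15), and the list gave a camera adjusted p of 0.315. The 13 neural stem cell markers had a median of 0.04 (camera adjusted p = 0.496). Adjusted over the list alone, Slc1a2 was the 1 astrocyte marker called, and 0 markers of mature oligodendrocytes or neural stem cells were.

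**Figure D2:**
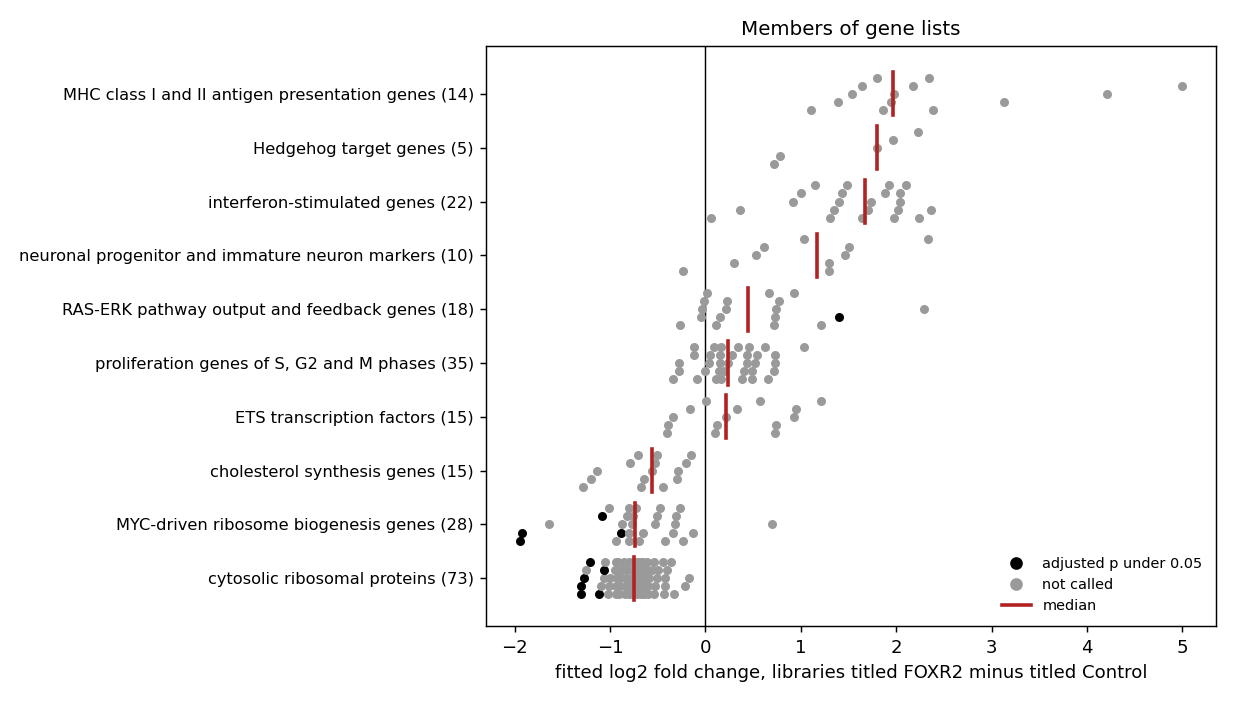
Fitted log2 fold change (horizontal axis, libraries titled FOXR2 minus titled Control) of each tested member of the 9 lists called by camera and of the ETS factors, with black points for genes called over all genes, gray points for the others and red bars for list medians. All 73 ribosomal protein genes lie below 0 with a median of -0.75, and the 14 MHC genes above it with a median of 1.96. The deposited sheet turns these signs round.

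Antigen presentation and interferon-stimulated genes were called higher as lists, but not in all libraries titled FOXR2. The 14 tested MHC genes were all fitted above 0 with a median log2 fold change of 1.96, and the 22 interferon-stimulated genes likewise with 1.67 (camera adjusted p = 2.06e-05 and 5.37e-05). With an estimated correlation the adjusted p was 0.619 and 0.640. No member of either list was called over all genes, and 9 MHC genes and 0 interferon-stimulated genes were called adjusted over the list alone. The sum of H2-K1, H2-D1 and B2m, of MHC class I, was 5127 CPM in FOXR2 replicate 2 and 6917 in FOXR2 replicate 3, but 1022 in FOXR2 replicate 1 and 886, 881 and 1922 in Control replicates 1, 2 and 3. Isg15, a ubiquitin-like protein induced by interferon, stood at 300.2 and 222 CPM in FOXR2 replicates 2 and 3, 30.5 in FOXR2 replicate 1 and 26.2 to 57.6 in those titled Control (log2 fold change 2.02 ± 0.74, edgeR adjusted p = 0.154). Irf7 had a log2 fold change of 2.24 ± 0.84 (adjusted p = 0.161).

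FOXR2 replicate 2 also stood apart in microglia and macrophage markers. The sum of 18 of these markers was 1590 CPM there and 7.30 to 16.0 in the other libraries. C1qa reached 228 CPM and Csf1r 125 in this library. H2-Aa, of MHC class II, stood at 60.2 CPM in this library, 5.84 in FOXR2 replicate 3 and 0.783 in FOXR2 replicate 1. H2-Eb1, also of class II, was alike in FOXR2 replicates 1, 2 and 3 (2.61, 2.59 and 2.77 CPM). Control replicates 1, 2 and 3 held 0.540, 0.596 and 0.871 (edgeR adjusted p = 0.0604). As a list the 6 tested markers were not called (median log2 fold change 2.47, camera adjusted p = 0.154), and without FOXR2 replicate 2 the median was -0.29. The list was called higher without FOXR2 replicate 1 or 3, with no filter and with animal sex as a covariate (camera adjusted p = 0.00481, 0.000411, 0.00656 and 0.024). Without FOXR2 replicate 2 the MHC and interferon lists kept their calls at the preset correlation, with medians of 1.52 and 1.06 (camera adjusted p = 0.00363 and 0.0204). These calls leaned on FOXR2 replicate 3. Interferon-stimulated genes summed to 3287 CPM there and to 630 in FOXR2 replicate 1, within the 511 to 1070 of the libraries titled Control.

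**Figure D3:**
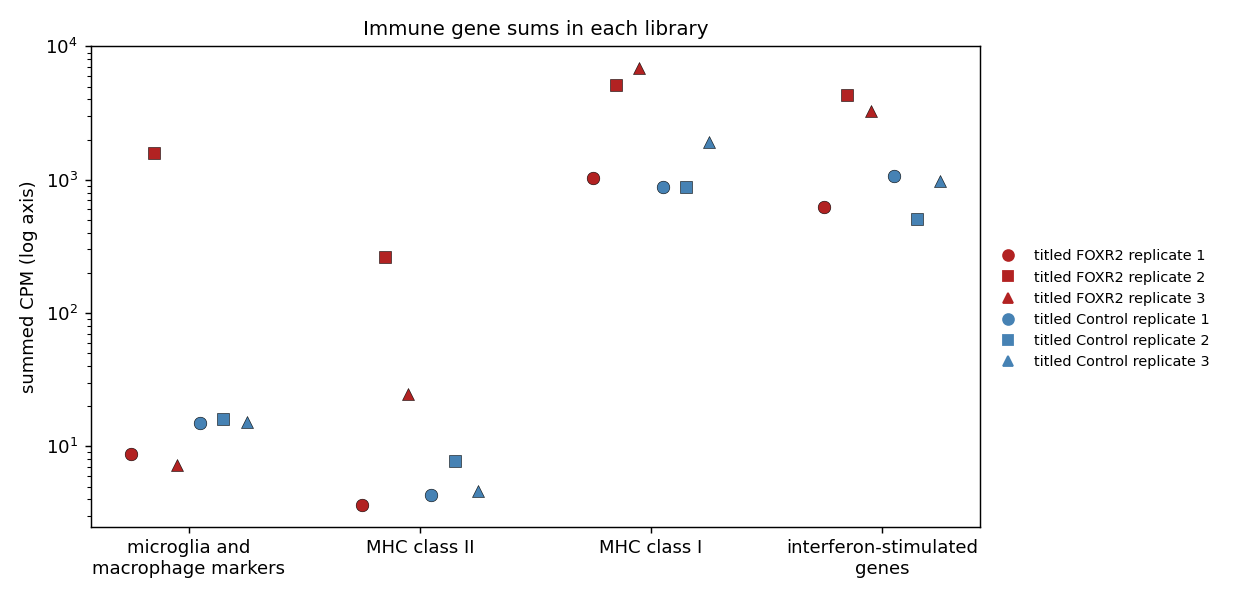
Summed CPM (vertical log axis) of 18 microglia and macrophage markers, MHC class II genes (H2-Aa, H2-Ab1 and Cd74), MHC class I genes (H2-K1, H2-D1 and B2m) and interferon-stimulated genes, with 1 point per library, red for titled FOXR2 and blue for titled Control. FOXR2 replicate 2 stands at 1590 CPM for the myeloid markers where no other library exceeds 16.0, and FOXR2 replicates 2 and 3 hold the highest MHC class I sums, 5127 and 6917.

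ETS transcription factors, the family named in the title of the series, were not called. Of 15 tested members 11 were fitted above 0 with a median log2 fold change of 0.22, and 0 were called by edgeR either over all genes or adjusted over the list alone. The list gave a camera adjusted p of 0.323. No list of ETS target genes was tested, so these transcript levels say nothing on ETS activity. Ets1 stood at 102 ± 27.3 against 52.7 ± 23.0 CPM, Elk3 at 38.7 ± 16.2 against 20.4 ± 8.10 and Etv3 at 27.8 ± 1.63 against 36.7 ± 1.45 (SD, n = 3 each; edgeR adjusted p = 0.184, 0.223 and 0.197).

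Output genes of RAS-ERK signaling, which lies downstream of Pdgfra, were called higher by camera (18 tested, 14 fitted above 0, median 0.45, adjusted p = 0.0176), with an adjusted p of 0.619 with an estimated correlation. Of them Phlda1 was called, at 155 ± 13 against 58.9 ± 18.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.0462), and 2 were called adjusted over the list alone. Epha4 had a log2 fold change of 2.29 ± 0.53 (adjusted p = 0.0648) and Ccnd1 of 0.93 ± 0.36 (adjusted p = 0.171). Without FOXR2 replicate 1, FOXR2 replicate 3 or Control replicate 3 this list lost its call (medians of 0.32, 0.30 and 0.37, adjusted p = 0.121, 0.0559 and 0.134), and without FOXR2 replicate 2 or Control replicate 2 its median was 0.73 and 0.78. With no filter on low counts and with animal sex as a covariate its median was 0.21 and 0.30 (camera adjusted p = 0.0488 and 0.0468).

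A list of Hedgehog pathway genes was also called higher by camera (5 tested, median 1.80, adjusted p = 0.0303; 0.596 with an estimated correlation). It holds the co-receptor genes Cdon and Boc beside target genes, so it does not measure pathway output alone. No member was called over all genes and 2 were adjusted over the list alone. The receptor gene Ptch1 stood at 97.9 ± 11.1 against 56.9 ± 14.0 CPM (edgeR adjusted p = 0.0952), and Cdon, Gli2, Hhip and Boc had log2 fold changes of 2.23, 1.97, 1.80 and 0.72. Without FOXR2 replicate 3 those of Gli2, Hhip and Boc were 0.95, 0.42 and 0.016, and without FOXR2 replicate 1 that of Cdon was 1.06. The Hedgehog call was lost without FOXR2 replicate 1, FOXR2 replicate 3 or Control replicate 3 (medians of 1.06, 0.69 and 1.49, adjusted p = 0.0595, 0.0651 and 0.134), and also with no filter on low counts, with animal sex as a covariate or with the length and GC offset (adjusted p = 0.324, 0.0809 and 0.0708, with medians of 0.76, 1.35 and 1.49). Cell cycle genes had a median of 0.24 (35 tested, 28 above 0, camera adjusted p = 0.0303; 0.790 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Rrm2, Cenpe and Nusap1, which had the smallest adjusted p, had log2 fold changes of 1.03, 0.73 and 0.49. The cell cycle call was lost without FOXR2 replicates 1 or 2 or Control replicates 2 or 3 (medians of 0.25, 0.06, 0.16 and 0.05, adjusted p = 0.121, 0.253, 0.113 and 0.633), and with animal sex as a covariate (adjusted p = 0.0809). Its median was 0.39 without FOXR2 replicate 3 and 0.60 without Control replicate 1.

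The other signaling lists gave no call with all libraries. Of 7 WNT targets the feedback inhibitor gene Nkd1 was called higher at 43.0 ± 26.7 against 5.75 ± 1.98 CPM (edgeR adjusted p = 0.0489), 2 were called higher and 1 lower adjusted over the list alone, and Axin2 had a log2 fold change of 2.27 ± 0.63 (adjusted p = 0.0920; list camera adjusted p = 0.0954). Of 19 hypoxia genes the histone demethylase gene Kdm3a was called higher at 142 ± 22.9 against 67.6 ± 10.3 CPM (adjusted p = 0.0489), and the list gave a camera adjusted p of 0.496. Notch pathway genes (9 tested, median 0.40, camera adjusted p = 0.265) had their smallest adjusted p in Notch1, at 253 ± 42.8 against 136 ± 5.16 CPM (SD, n = 3 each; edgeR adjusted p = 0.0552), and their largest fitted change in Hey2, a log2 fold change of 1.30 ± 0.67 (adjusted p = 0.275). Across fits without 1 library the Notch median ran from -0.01 to 0.80, and with animal sex as a covariate it was -0.17. Hey2 was fitted at 0.93 without Control replicate 2 and at 2.49 without Control replicate 3. Camera adjusted p was 0.474 for 19 p53 targets, 0.051 for 14 fibroblast and matrix genes (median log2 fold change 0.94), 0.751 for 19 mesenchymal glioma genes and 0.496 for 12 immediate early genes. Adjusted over the list alone, 1 hypoxia gene and 1 Notch pathway gene were called higher, and 0 p53 targets, mesenchymal genes or immediate early genes were called. In the matrix list 5 members were called higher adjusted over the list alone, and Col5a1, Fn1 and Postn had log2 fold changes of 2.82, 1.79 and 4.27 with edgeR adjusted p of 0.0661, 0.0741 and 0.0851. Camera called the matrix list higher without FOXR2 replicate 1, FOXR2 replicate 3 or Control replicate 2 (adjusted p = 0.00538, 0.0238 and 0.0158), with no filter and with animal sex as a covariate (adjusted p = 0.0191 and 0.0158). Without FOXR2 replicate 2, the library apart in macrophage markers, its median was 0.15 and it was not called (adjusted p = 0.139). Without FOXR2 replicate 2 it called the WNT list higher (adjusted p = 0.00186) and the mesenchymal list lower (adjusted p = 0.0252), and without FOXR2 replicate 3 the immediate early list higher (adjusted p = 0.0447).

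Other cell types that a brain tumor can hold left few counts. Summed endothelial markers (5 tested, camera adjusted p = 0.773) lay between 22.1 and 39.4 CPM in all libraries, mural cell markers between 16.9 and 36.8, T and natural killer cell markers between 3.72 and 10.1, and neutrophil markers between 2.77 and 18.7. The endothelial Egfl7 and the mural Notch3, neither highest in FOXR2 replicate 2, held much of their sums. Pecam1, Cdh5 and Pdgfrb reached 2.02, 1.52 and 3.35 CPM in FOXR2 replicate 2. In the other libraries they were at most 0.391, 0.116 and 0.12, so like sums do not show like vascular content. Red blood cell genes stood at 0.0653 to 0.30 CPM, with 0 counts on each hemoglobin gene, whose near-identical copies leave this uncertain. Ependymal and choroid plexus markers summed to 3.52 to 20.3 CPM, the highest in FOXR2 replicate 2. Ventral forebrain interneuron markers summed to 85.3, 54.9 and 60.8 CPM in FOXR2 replicates 1, 2 and 3 and to 22.6, 42.7 and 35.8 in Control replicates 1, 2 and 3, sums that were not tested. Of the 4 tested members 0 were called by edgeR over all genes and 1 adjusted over the list alone. Maf stood at 11.3 ± 4.74 against 2.36 ± 1.13 CPM (SD, n = 3 each; edgeR adjusted p = 0.0659), and Gad1, Erbb4 and Npy had log2 fold changes of 1.81 ± 0.94, 0.40 ± 0.30 and -2.45 ± 1.37 (adjusted p = 0.279, 0.444 and 0.308). Gad1 turned to -0.020 without FOXR2 replicate 1 and Npy to 0.50 without Control replicate 3. With all libraries and the filter on low counts, these lists except the endothelial one had fewer than 5 tested members and no list test. The interneuron list passed that minimum with no filter, where camera called it higher (median 1.92, adjusted p = 0.00656), and in each fit without 1 library. It was called higher without FOXR2 replicate 2, Control replicate 2 or Control replicate 3 (adjusted p = 0.00325, 0.0186 and 0.0353) and not without FOXR2 replicate 1, FOXR2 replicate 3 or Control replicate 1 (adjusted p = 0.274, 0.153 and 0.0843). With no filter the T and natural killer cell, neutrophil, mural and ependymal lists were not called (camera adjusted p = 0.386, 0.513, 0.526 and 0.414). By Xist and Y-linked genes FOXR2 replicates 1 and 3 and Control replicate 1 came from males and the others from females, so sex was not balanced between the groups. The list of these 5 sex-linked genes was not called (camera adjusted p = 0.496). It holds Xist beside Y-linked genes, which move in opposite directions, so this does not show balance.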

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

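Animal sex, the length and GC offset and the sheet's groups were chosen after seeing the data. DESeq2 called 947 genes higher and 947 lower, 736 and 444 of them at least 2-fold, and total-count scaling 119 lower. With animal sex as a covariate 7 were higher and 0 lower (7 and 0 at least 2-fold; 2398 at an unadjusted p under 0.05 in edgeR). Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.01, -0.23 and -0.01. With the replicate block edgeR called 0 higher and 0 lower (0 and 0 at least 2-fold; 2652 at an unadjusted p under 0.05, smallest adjusted p 0.0533). Camera with the block called the mature neuron list higher (median 0.39, adjusted p = 0.0196) and changed no other list's call. Across fits without 1 library, counts ran from 1 to 123 higher and 0 to 82 lower, with the same ranges for at least 2-fold changes. With the sheet's groups 181 are higher and 119 lower (165 and 112 at least 2-fold), and 3 lists higher and 6 lower. Camera called 6 lists higher and 3 lower, 0 and 0 with an estimated correlation, and fry 1 and 0. The cause of these shifts was not tested, except that the sheet exchanges the groups. The other settings, RLE factors, no filter, limma-voom and the length and GC offset, gave 85 to 104 genes higher and 128 to 158 lower. The median of all genes was 0.01 in edgeR and 0.12 in DESeq2, which tested more low genes.

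Of 88 named genes compared, 0 changed direction under an edgeR or limma-voom setting that kept all libraries and the titles' groups, and 0 of the 86 with an adjusted p in DESeq2 did so there. Laptm5, a microglia marker, turned to -0.26 without FOXR2 replicate 2, the library that held nearly all of its counts, Gad1 to -0.020 without FOXR2 replicate 1 and Npy to 0.50 without Control replicate 3. Calls were gained by Aldh1l1 and Col5a1 without FOXR2 replicate 2 (-2.79 and 3.245, edgeR adjusted p = 0.0353 and 0.0437). Dcx gained one without Control replicate 3 (3.35, edgeR adjusted p = 0.0321). At this spread 2-fold changes were seldom recovered in simulated counts (2%), so missing calls do not show that genes were alike. The share in the real libraries can differ, as simulated genes varied independently and few were changed.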

Other observations

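The protocadherin, metallothionein and Myc family genes here were chosen after their values were seen. Of 44 tested genes of the clustered protocadherins, cell surface molecules that give neurons their identity, 37 were fitted above 0 with a median log2 fold change of 1.43, and 7 were called higher and 0 lower, or 4 higher with an offset for transcript length and GC. As the family was picked for its high members, no test of it as a group is given. Pcdhb2 stood at 18.3 ± 2.67 against 0.883 ± 0.489 CPM and Pcdhb14 at 12.1 ± 2.72 against 2.38 ± 0.590 (SD, n = 3 each; edgeR adjusted p = 0.0283 and 0.0388). These genes have close copies, and those of the alpha and gamma clusters also share exons, so reads cannot be given to single members with certainty. The metallothionein genes Mt1 and Mt2 were lower, at 248 ± 37.4 against 717 ± 180 CPM and 196 ± 37.9 against 730 ± 35.5 (edgeR adjusted p = 0.0396 and 0.0283). Camera called the ribosome biogenesis list lower at the preset correlation but not with an estimated one (adjusted p = 0.596). Beside it, Mycn averaged 8.11 ± 6.78 against 0.989 ± 0.538 CPM and Myc 106 ± 27.1 against 63.6 ± 2.69 (edgeR adjusted p = 0.0688 and 0.102).

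The tests of scaling, microglia RNA and exchanged titles, and those of other splits except for the lists, were chosen only after the result was seen. Ribosomal protein and ribosome biogenesis genes were lower as lists at the preset correlation, but not with an estimated one (camera adjusted p = 0.596 for each). Most clustered protocadherins were fitted above 0, and fold changes rose with transcript length across genes (Spearman 0.22, genes not being independent replicates). An offset for transcript length and GC left the ribosomal protein median at -0.54 (from -0.75), that of ribosome biogenesis at -0.70 (from -0.74) and that of protocadherins at 1.21 (from 1.43). Their standard errors of 0.04, 0.14 and 0.34 take the genes as independent and do not measure the spread between libraries. The trend as fitted did not remove these medians. It used the longest transcript of each symbol, which need not be the one expressed, so a length effect is not settled. The calls of all 6 ribosomal protein genes ended with the offset, as their folds became smaller (Rps21 from -1.30 ± 0.206 to -1.02 ± 0.199, Rps18 from -1.27 ± 0.223 to -1.06 ± 0.231, Rpl37a from -1.12 ± 0.202 to -0.84 ± 0.216), so part of these folds went with the trend. So did those of 1 of 4 called members of the biogenesis list, Phb2, the gene of a mitochondrial protein (-0.88 ± 0.170 to -0.81 ± 0.201), and 3 of 7 protocadherins, Pcdha3 (6.10 ± 1.27 to 5.94 ± 1.27), Pcdhb14 (2.34 ± 0.353 to 1.99 ± 0.391) and Pcdhgc4 (3.83 ± 0.726 to 3.65 ± 0.715). Under other scalings the ribosomal protein median nearest 0 was -0.71, but these moved the median of all genes only from 0.01 to 0.03 and 0.05, so scaling was not put to a test and stays open. Reads shared with ribosomal pseudogenes and a difference between the tumor groups stay open and were not tested.

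MHC class II genes summed to 262 CPM in FOXR2 replicate 2 and 24.6 in FOXR2 replicate 3, against 3.65 to 7.75 in the others, and MHC class I and interferon-stimulated genes were high in FOXR2 replicates 2 and 3. Microglia or macrophage RNA is a candidate explanation for the class II genes of FOXR2 replicate 2, as 18 myeloid markers summed to 1590 CPM there and to at most 16.0 in any other library. It is argued against for class I and class II in FOXR2 replicate 3, where they summed to 7.30 CPM, below the highest library titled Control, beside an MHC class I sum of 6917 CPM. FOXR2 replicate 1 had neither high sum, so the group alone does not account for these sums. H2-Eb1, a class II gene outside the sum, differed from them. It stood at 2.61, 2.59 and 2.77 CPM in FOXR2 replicates 1, 2 and 3 and at most 0.871 in the libraries titled Control. An interferon response of the tumor cells themselves stays open as an untested hypothesis.

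The titles and the deposited sheet name opposite groups for 6 of 6 libraries. Titles exchanged between the groups is a possible explanation, but the Foxr2 counts overlapped (exact two-sided permutation p = 0.8), so an error in the titles and one in the sheet cannot be told apart. The gene had 51 counts in all. A construct of another species or without the mouse untranslated regions need not add to them, so this test could not decide between the sources.

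With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 119 genes higher and 181 lower, the highest other split 4 in 1 direction, that of FOXR2 replicates 1 and 3 and Control replicate 1 against the rest, which is also the split by animal sex. For at least 2-fold changes these were 112 and 165, and 4. Of the 10 splits 1, the real one, gave as many genes in each of these 4 counts. For the lists, 8 of the 10 splits gave as many as the 6 called higher and 9 as many as the 3 called lower, with up to 9 in another split. Both directions together, camera called 9 lists in the real split and 3 to 15 in the others.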
